A study of Homo sapiens with 12 samples.

How the data were processed

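Gene expression was measured in mammospheres, floating spheres grown in low-attachment plates, of MCF7 cells, an established luminal breast cancer line. Cells carried either a Neo selection gene alone (control cells) or the thyroid hormone receptor β (TRβ cells), and each line was profiled without and with 25 nM triiodothyronine (T3), the active thyroid hormone. The labels assign 12 arrays to 4 groups of 3. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The medium contained the B27 supplement, whose standard formula includes T3, so the groups called untreated received no added T3 and are not known to be free of the hormone.

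Total RNA was converted to biotin-labelled single-stranded cDNA for Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values are on the log2 scale, with 1 value per transcript cluster, called a probe set here. RMA, which combines background correction, quantile normalization and probe summary, is named in the submitters' processing notes. The software, its version, the filters and the genome build are not given in the sources used here. The values ran from 2.14 to 19.98, and 2603 values in 302 probe sets lay above 16, the highest log2 level that a 16-bit scanner can record. A rescaling step that is not stated may therefore have been used, and fold changes are given on the deposited scale. Array medians lay between 4.38 and 4.58, so the arrays did not share a single distribution as deposited. The number of arrays limits the precision. No value was missing and no array was identical to another.

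The deposited table held 67528 probe sets. The platform annotation gave 23781 of them 1 gene symbol and 1543 several symbols, and 42204 are unnamed here. Of the probe sets with 1 symbol, 21497 had a gene identifier found in a RefSeq gene table (GRCh38.p14), which was used for names and gene types only, and no symbol changed. A gene was a probe set with exactly 1 symbol, and for the 479 genes with more than 1 such probe set the one with the highest mean over all arrays was used. This gave 22465 genes, with no filter on low values. No coordinates are given because no build is named for the arrays' values.

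A linear model with a coefficient for each group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and 5 contrasts were tested 2-sided with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The contrasts were the T3 effect in TRβ cells, the T3 effect in control cells, the difference of these effects (interaction), and the TRβ effect without and with added T3. The TRβ effects and the interaction set the TRβ line against the control line. No label names independent transductions, so the receptor cannot be told apart from other differences between the lines. Adjusted p-values below come from this fit unless stated otherwise. Values after ± are SDs where they follow the log2 level of a group, and standard errors of the fit where they follow a change, unless marked SD. Gene lists were fixed from textbook knowledge before the data were examined. The 27 lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over 135 tests, with camera at an estimated correlation and fry as alternatives. A list of nuclear retained and short-lived RNA had too few measured members and was not tested. Members of a list past the threshold were counted over all genes and again adjusted over the list alone.

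Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls past the threshold for the T3 effect in TRβ cells and for both TRβ effects, and the 5 largest each way for the other contrasts. Except for the interaction, the 3 arrays of one group had to lie on one side of those of the other. THRB, THRA, ESR1, PGR, KLF9 and DIO1 could be named whatever their value, and so could up to 4 members of each list with the smallest adjusted p. Small RNA genes and unnamed loci counted in the rule but could be left out, and genes with close relatives or near-identical copies are named as uncertain. Genes named outside the rule are marked as chosen after their values were seen.

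The steps were tested on simulated data, with 200 of 22465 genes changed in arrays drawn from each gene's real mean and its spread pooled over the 4 groups. The larger spread of the control group was not kept, so the shares recovered in comparisons with that group may be too high. For the T3 effect in TRβ cells, 86.6% of genes changed by 1 on the log2 scale and 40.3% of those changed by 0.5 were recovered, and 14 unchanged genes were called. For the T3 effect in control cells the shares were 76.1% and 43.3%, with 6 unchanged genes called. For the difference of the T3 effects they were 68.7% and 22.4%, with 11 unchanged genes called. For the TRβ effect without T3 they were 86.6% and 44.8%, with 4 unchanged genes called, and for the TRβ effect with T3 they were 83.6% and 52.2%, with 7. A planted list of 30 genes raised by 0.5 was called in each of the 5 contrasts, and 0 unchanged lists were. Genes were drawn independently of each other. The simulation therefore does not show how often lists or genes that vary together would be called by mistake. Most contrasts called more genes than the 200 changed here, and the adjustment depends on that number. The shares recovered and the unchanged genes called therefore do not carry over to those contrasts.

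Alternatives fixed before the data were examined were leaving out the 40% of genes with the lowest mean, adjusting over all probe sets, centring arrays on their medians, repeating quantile normalization, averaging a gene's probe sets, a trended and robust variance prior, array weights, fitting only the groups compared, the replicate number as a block, a minimum change of 1.5-fold, an adjusted p threshold of 0.01, and leaving out each array in turn. Cyclic loess normalization was added after seeing the data, because dim genes were shifted on the arrays of TRβ cells with T3. For lists, a median was also set beside those of 1000 random lists matched on mean level in 50 bins.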

Results

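The 12 arrays compared mammospheres of MCF7 control and TRβ cells, each without added hormone and with 25 nM T3, in 3 replicates per group. THRB, the gene of the transduced receptor, was measured at a log2 level of 5.16 ± 0.11 (SD, n = 3) in control cells and 5.19 ± 0.05 in control cells with T3. In TRβ cells it was 6.09 ± 0.13 (SD) without and 6.15 ± 0.10 (SD) with T3. The THRB values of all 6 TRβ arrays lay above those of the 6 control arrays, and the rise in TRβ cells without T3 was 1.91-fold (log2 change 0.94 ± 0.09, adjusted p = 5.7e-04 by limma with Benjamini-Hochberg adjustment). The level in control cells was near the median over genes on those arrays (4.96 to 5.02). No background level is given, so the size of the rise is uncertain. THRA, which encodes the related receptor α, did not pass the threshold in any of the 5 contrasts.

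The first principal component over the 22465 genes held 44.0% of the variance and set the TRβ arrays with T3, at scores of 40.36 to 47.62, apart from the other 9 arrays, at −31.87 to −4.34. The next component held 18.8% and set control replicate 2 apart, at 46.28. That array correlated at r = 0.965 across probe sets with both other control arrays, which correlated with each other at 0.989. The median SD of a gene was 0.160 in the control group and 0.093, 0.093 and 0.104 in the control with T3, TRβ and TRβ with T3 groups. Without control replicate 2, one of the planned left-out arrays and doubted after seeing the data, the numbers of genes past the threshold rose from 4687 to 6300 for T3 in TRβ cells, from 26 to 72 for T3 in control cells, from 2674 to 4433 for the difference of these effects, from 745 to 1253 for TRβ without T3 and from 3592 to 5087 for TRβ with T3.

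**Figure D1:**
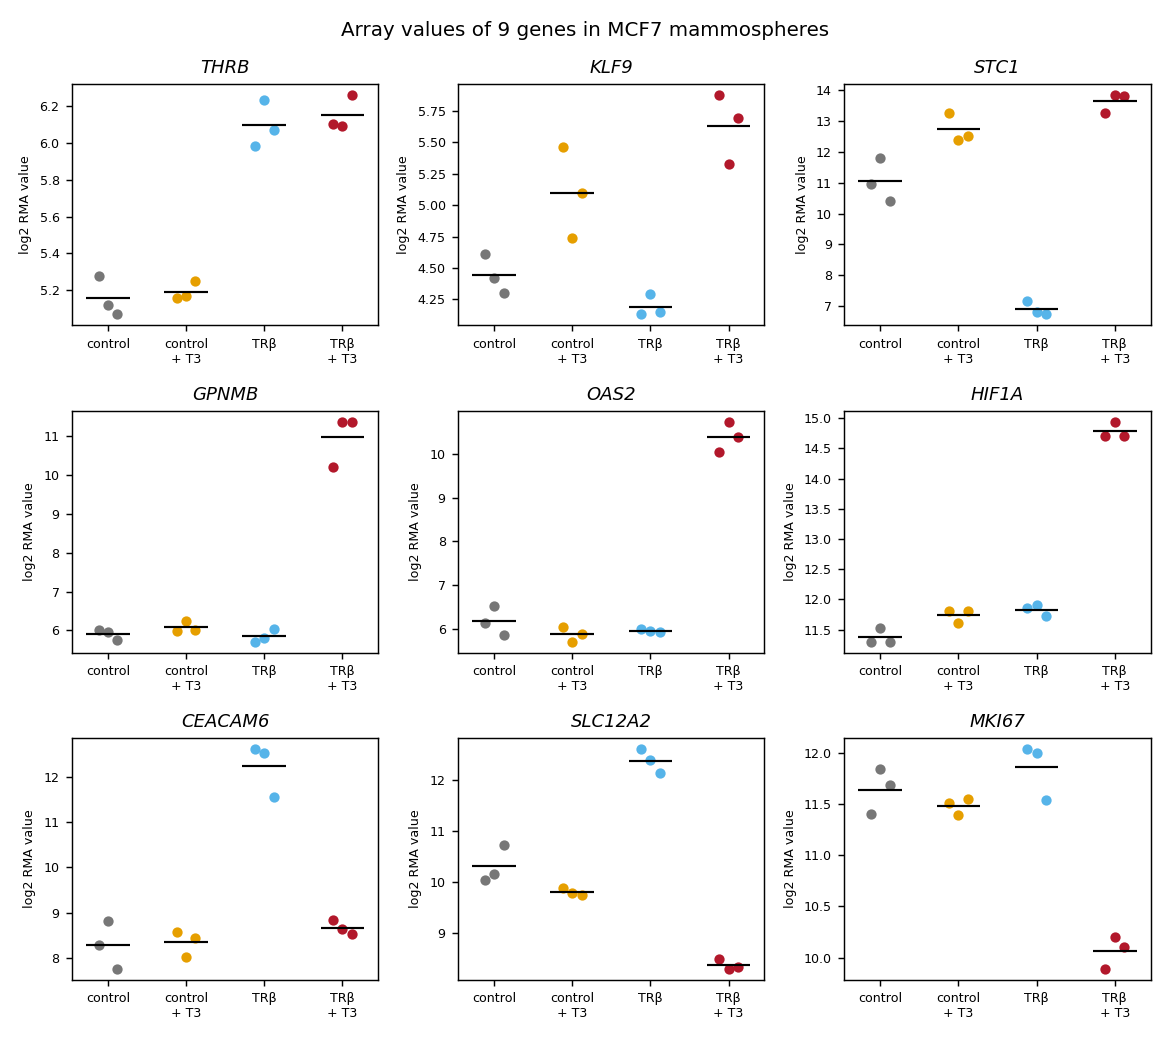
Log2 RMA values (vertical axes, each with its own range) of 9 genes on each array (points) in the 4 groups (horizontal axes), with the group mean as a bar (n = 3). STC1 averaged 6.91 in TRβ cells and 13.65 with T3, and CEACAM6 and SLC12A2 were high in TRβ cells without T3 and lower with it.

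The comparison of TRβ cells with and without T3 asked how the ligand changes expression in cells that carry the transduced receptor. Genes of the interferon response rose, genes of DNA replication and mitosis fell, and several estrogen response and luminal genes fell. The largest rise was that of STC1, which encodes the secreted glycoprotein stanniocalcin-1, from a log2 level of 6.91 ± 0.24 (SD, n = 3) to 13.65 ± 0.34, a log2 change of 6.74 ± 0.34 or 107-fold (adjusted p = 9.4e-07). GPNMB, a transmembrane glycoprotein, rose 34.9-fold, and ANXA1, the phospholipid-binding protein annexin A1, rose by 3.89 ± 0.35 on the log2 scale. CASP14, a caspase of epidermal differentiation, rose from 10.07 ± 0.53 (SD) to 14.07 ± 0.24. The largest falls were those of UGT2B15, an enzyme that conjugates steroids (log2 change −4.22 ± 0.19, adjusted p = 3.4e-07), SLC12A2, a sodium, potassium and chloride cotransporter (−4.01 ± 0.17), and DKK1, a secreted Wnt inhibitor (−3.58 ± 0.18). The adhesion molecules CEACAM6 and CEACAM5 fell by 3.57 and 3.51, and CDSN, the gene of corneodesmosin, fell 10.9-fold (adjusted p = 2.5e-05). SPTSSB, a subunit of serine palmitoyltransferase, fell by 3.37. UGT2B15, CEACAM5, CEACAM6 and the pseudogenes WFDC21P (−3.44 ± 0.30) and TMSB4XP8 (−3.41 ± 0.24) have close relatives in the genome, so the gene behind these signals is uncertain. In all, 1861 genes were higher and 2826 lower with T3, of which 274 and 514 changed at least 2-fold.

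All 36 measured interferon response genes rose with T3 in TRβ cells, over all genes and also adjusted over the list alone, with a median log2 change of 2.06. OAS2, an enzyme that activates RNA degradation in antiviral defence, rose by 4.44 ± 0.19, IFIH1, a sensor of double-stranded RNA, by 3.98 ± 0.26, and OASL, IFI27 and IFI6 by 3.65, 3.75 and 4.41. IFI44L, HERC6 and IFIT3 rose by 2.84, 2.52 and 2.33. The list had an adjusted p = 4.1e-32 in camera with the preset correlation and an adjusted p = 0.17 with an estimated correlation. IFNL1, which encodes a type III interferon and belongs to a family of close relatives, rose by 3.57 ± 0.35.

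Genes of the cell cycle fell together. Of 29 measured G2 and mitosis genes 27 fell (29 adjusted over the list alone), with a median log2 change of −1.31, among them CCNA2 (−1.95 ± 0.12), NDC80 (−1.97 ± 0.15) and MKI67 (−1.80 ± 0.15), which encode cyclin A2, a kinetochore protein and the proliferation marker Ki-67. Of 28 S phase and replication genes 24 fell (24 adjusted over the list alone), with a median of −0.87, among them CDC6 (−1.76 ± 0.15), TYMS (−1.44 ± 0.11) and CDC45 (−1.25 ± 0.12). Camera gave adjusted p-values of 1.0e-20 and 6.0e-16, and both lists had an adjusted p = 0.17 with an estimated correlation. Medians of genes matched on level were −0.25 and −0.21 for these lists.

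Of 33 estrogen response genes 15 fell and 2 rose (18 and 2 adjusted over the list alone). ESR1, the gene of the estrogen receptor α, fell by 1.11 ± 0.24 (adjusted p = 0.0092) and PGR, the gene of the progesterone receptor, by 0.34 ± 0.07 (adjusted p = 0.0058). The transcription factor genes MYBL1, XBP1 and MYB fell by 1.69, 1.65 and 1.39. Of 21 luminal epithelial genes 10 fell and 1 rose (14 and 2 adjusted over the list alone), including the adhesion molecule gene EPCAM (−0.82 ± 0.07), AGR2 (−1.28 ± 0.13) and the keratin gene KRT8 (−0.76 ± 0.10). The adjusted p-values of these lists were 6.8e-05 and 5.2e-05, and 0.46 and 0.33 with an estimated correlation. In the luminal list control replicate 2 lay above the mean of the other control arrays in 16 of 21 members, with a median difference of 0.46. That array enters the T3 effect in TRβ cells only through the shared spread.

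Known thyroid hormone targets moved in both directions. Of 25 measured response genes 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0011, and 0.17 with an estimated correlation). KLF9, a transcription factor induced by the hormone in many tissues, rose by 1.44 ± 0.18 (adjusted p = 3.1e-04), ME1, the cytosolic malic enzyme, by 2.23 ± 0.19 and THRSP, a regulator of lipid synthesis, by 1.11 ± 0.09. MYH6, a cardiac myosin gene, rose by 1.03 ± 0.08. DIO1, the gene of a deiodinase, changed by −0.16 ± 0.07 and did not pass the threshold (adjusted p = 0.14). Among the receptor's partners, the coactivator genes NCOA2 and NCOA1 fell by 0.82 and 0.77, and these were the 2 of 9 members past the threshold (camera adjusted p = 0.24). Of 11 transport and deiodination genes, the amino acid transporter gene SLC7A8 rose by 1.01 ± 0.18 and SLC7A5 fell by 1.26 ± 0.38 (camera adjusted p = 0.84). The counts of both lists were the same adjusted over the list alone.

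Metabolic and stress genes rose in part. Of 25 hypoxia response genes 12 rose and 5 fell, with HIF1A, the oxygen-regulated transcription factor, at 2.95 ± 0.10, VEGFA at 1.31 ± 0.12 and HK2, a hexokinase, 2.29-fold higher (list adjusted p = 0.0024, and 0.50 with an estimated correlation). Of 16 fatty acid synthesis genes 4 rose and 1 fell, including the lipid droplet gene PLIN2 (1.33 ± 0.09) and the triglyceride synthesis gene DGAT2 (1.74 ± 0.21), with list adjusted p = 0.039, and 0.50 with an estimated correlation. Of 21 amino acid and ER stress response genes 7 rose and 1, XBP1, fell. DDIT3, a stress-induced transcription factor, rose by 2.04 ± 0.18 (list adjusted p = 0.0093, and 0.41 with an estimated correlation). Of 16 p53 target genes 7 rose, among them the death receptor genes FAS (0.76 ± 0.08) and TNFRSF10B (0.57 ± 0.07), with list adjusted p = 7.9e-04, and 0.27 with an estimated correlation. Of 21 NF-κB target genes 8 rose, with TNFAIP3 2.83-fold higher and IRF1 at 0.93 ± 0.07, and IL6 fell by 0.59 ± 0.07 (list adjusted p = 0.011, and 0.50 with an estimated correlation). Adjusted over each list alone, 14 rose and 5 fell for hypoxia, 6 and 1 for fatty acid synthesis, 9 and 1 for stress response, 7 and 0 for p53 and 9 and 1 for NF-κB. The call of the fatty acid list was lost without control replicate 2, control replicate 3 or TRβ replicate 3, at adjusted p = 0.12, 0.053 and 0.11.

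The mammary stem cell and pluripotency list bears on the series' stated interest in self-renewal. Of its 24 measured genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.11. That median lay within those of most random lists matched on level (−0.06 to 0.13). The pluripotency factor gene SOX2 rose by 1.31 ± 0.18, ALDH1A3, an aldehyde dehydrogenase used as a stem cell marker, by 1.09 ± 0.14 and SOX9 by 0.48 ± 0.10, while the transporter gene ABCG2 fell by 0.60 ± 0.13. The list's adjusted p was 0.033, with an adjusted p = 0.24 with an estimated correlation, and after cyclic loess normalization, chosen after seeing the data, it was 0.13. Over all camera alternatives it ran from 0.021 to 0.24, and without replicate 3 of TRβ cells with T3 it was 0.056. Of 14 ErbB receptor and ligand genes 2 rose and 5 fell, including ERBB4 (−2.36 ± 0.17) and ERBB3 (−0.85 ± 0.14), and the list's median was 0.04 while its mean was −0.33 and camera did not call it (adjusted p = 0.59). Adjusted over the list alone 3 rose and 5 fell. Of 13 basal genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.24), with CDH3, the gene of P-cadherin, at 1.54 ± 0.23.

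Camera did not call the next 8 lists for T3 in TRβ cells. Members rose and fell, in that order, in 1 and 0 of 15 mesenchymal genes, 1 and 4 of 13 Wnt targets, 2 and 0 of 12 Notch targets, 3 and 4 of 18 TGF-β targets and 4 and 0 of 19 MAPK response genes. The counts were 2 and 5 of 17 cholesterol genes, 1 and 3 of 21 oxidative phosphorylation genes and 0 and 4 of 20 ribosome biogenesis genes. Adjusted over the list alone they were 2 and 1 for Notch, 4 and 5 for TGF-β and 2 and 7 for cholesterol, and as before for the others. The TGF-β list had a median of −0.03 and a mean of 0.07. After cyclic loess normalization the oxidative phosphorylation list was called as higher (median 0.24, adjusted p = 0.015, against 0.015 to 0.89 over all camera alternatives), as were the MAPK response genes (0.040, against 0.040 to 0.74), and the Wnt targets as lower (0.027, against 0.0091 to 0.42). With all probe sets used, the Wnt (0.0091), cholesterol (0.0099), thyroid hormone receptor (0.039) and ribosome biogenesis (0.048) lists were called as lower. That setting compares the lists with the 42204 unnamed probe sets too, whose median log2 change was 0.11, against 0.02 over the genes. A call as lower there may therefore come from this background. Among markers of other cell types, of 12 fibroblast markers 4 rose, of 13 immune cell markers 4 and of 10 endothelial markers 1, with ITGAM at 0.42 ± 0.07 and LUM at 0.32 ± 0.08. CD68, chosen after its values were seen, changed by 0.49 ± 0.17 without passing (adjusted p = 0.073) and had the highest change of the 35 markers after cyclic loess normalization, 0.61. Adjusted over the list alone 6, 6 and 0 rose. The fibroblast and immune lists had adjusted p-values of 0.013 and 0.0082 (0.27 and 0.41 with an estimated correlation), which were 0.27 and 0.16 after cyclic loess normalization and ran from 0.011 to 0.60 and from 0.0045 to 0.57 over all camera alternatives. The fibroblast median of 0.178 lay within those of most random lists matched on level (0.005 to 0.190). The immune median of 0.200 lay above them (0.010 to 0.187). The endothelial list was not called by camera (adjusted p = 0.36). Of the 13 lists camera did not call, fry, which tests whether a list's genes move one way on balance and compares them with no other genes, called 5, the basal (adjusted p = 2.4e-04), Wnt (3.7e-04), ErbB (9.4e-04), mesenchymal (0.0013) and thyroid hormone receptor (0.041) lists.

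The changes with T3 in TRβ cells depended on signal level, with a median log2 change of 0.10 in the tenth of genes with the lowest mean and −0.30 in the tenth with the highest. After cyclic loess normalization, chosen after seeing the data, 1550 genes were higher and 2052 lower, 2873 of them among the 4687, whereas centring each array on its median, which shifted the median over all genes by −0.13, gave 848 higher and 4473 lower. Without TRβ replicate 1 or 2 the count was 3033 or 2934.

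**Figure D2:**
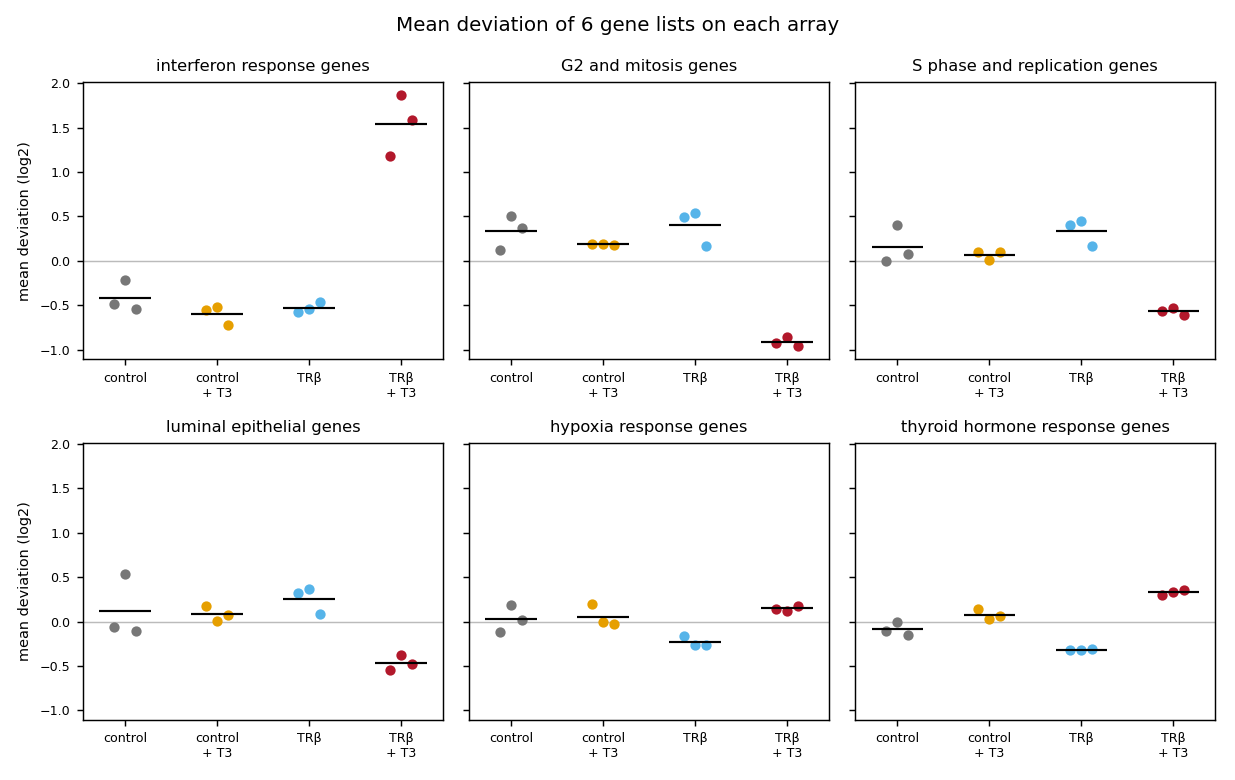
Mean log2 deviation of the members of 6 gene lists from their mean over all 12 arrays (vertical axes), per array (points) and group (horizontal axes), with the group mean as a bar (n = 3). The 3 arrays of TRβ cells with T3 lay above all others for the interferon response genes and below all others for the mitosis, S phase and luminal lists.

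In control cells, T3 moved few genes past the threshold. Of 22465 genes 21 were higher and 5 lower with T3 by limma with Benjamini-Hochberg adjustment, and 2284 had an unadjusted p under 0.05. Among genes past the threshold, the largest rise of a protein-coding gene was that of COLEC12, a scavenger receptor (log2 change 1.60 ± 0.19, adjusted p = 0.022), followed by the cytokine gene IL20 (1.21 ± 0.18, adjusted p = 0.044) and NET1, a guanine nucleotide exchange factor (2.30-fold, adjusted p = 0.016). The U1 pseudogenes RNU1-12P and RNU1-13P, which are near-identical copies with the same values on these arrays, rose by 1.67 and are counted separately among the 21. SPTSSB fell by 1.07 ± 0.16 and SPRR2G, of a family of close relatives, by 0.98 ± 0.10. Among thyroid hormone response genes THRSP rose by 0.73 ± 0.09 (adjusted p = 0.025), whereas STC1 at 1.69 ± 0.34 (adjusted p = 0.13) and KLF9 at 0.66 ± 0.18 (adjusted p = 0.24) did not pass. ESR1 changed by −0.12 ± 0.24 and PGR by −0.16 ± 0.07, and neither passed.

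No list had more than 1 member past the threshold for T3 in control cells. That member was THRSP, which belongs to the thyroid hormone response and fatty acid synthesis lists (camera adjusted p = 0.099 and 0.98). Adjusted over the list alone, 3 of 25 thyroid hormone response genes, 2 of 18 TGF-β targets and 1 each of the fatty acid synthesis, stress response, p53 and oxidative phosphorylation genes were higher, and 1 each of the stress response and NF-κB genes lower. Camera called 5 lists as lower, the NF-κB targets (median −0.13, adjusted p = 7.2e-05), interferon response genes (−0.12, 4.4e-04), G2 and mitosis genes (−0.14, 0.0070), estrogen response genes (−0.08, 0.011) and S phase genes (−0.10, 0.030). None of their members passed over all genes, and their adjusted p-values with an estimated correlation were 0.35, 0.61, 0.56, 0.64 and 0.64. Without control replicate 2 the median of the estrogen list was 0.04, and the estrogen, S phase and G2 lists had adjusted p = 0.89, 0.75 and 0.18. The G2 list had 0.13 without control replicate 3, and the estrogen and S phase lists had 0.066 and 0.17 without replicate 2 of control cells with T3. Camera did not call the other 22 lists, of which fry called 1, the thyroid hormone response genes (adjusted p = 0.0052). Among these 22, camera called the cholesterol genes as lower after cyclic loess normalization (median −0.12, adjusted p = 0.037, against 0.037 to 0.86 over all camera alternatives), the TGF-β targets as higher without control replicate 2 (0.026) and the thyroid hormone response genes as higher after repeated quantile normalization (0.046, against 0.046 to 0.32).

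The count of 26 genes for T3 in control cells rested on single arrays. It was 0 without control with T3 replicate 3, 4 without replicate 2 and 7 without replicate 1 of that group, 72 without control replicate 2, and 11, 13 and 10 without TRβ replicates 1, 2 and 3, which enter through the shared spread. With the 6 arrays of control cells alone it was 0, and repeated quantile normalization and cyclic loess gave 25 higher and 11 lower and 22 higher and 10 lower.

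**Figure D3:**
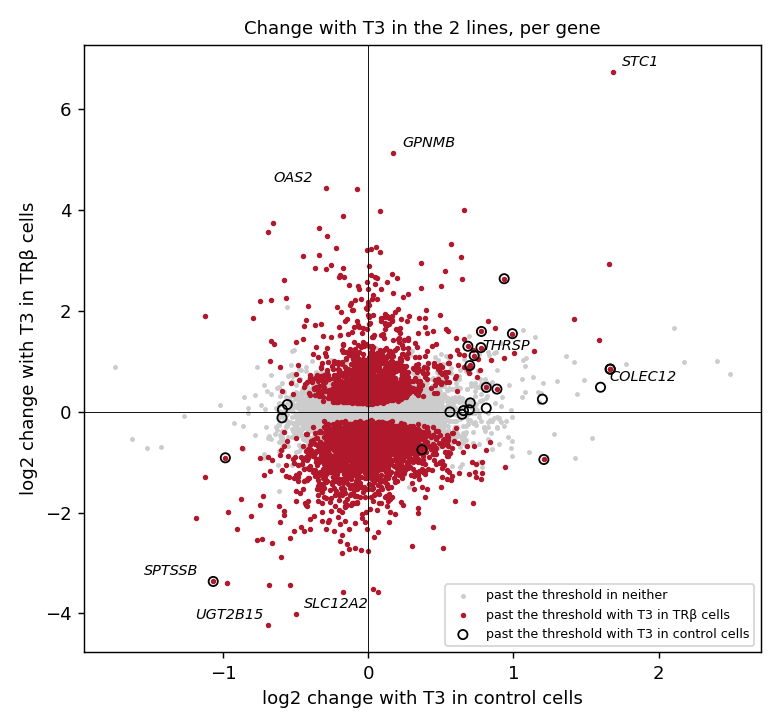
Log2 change with T3 in control cells (horizontal axis) and in TRβ cells (vertical axis) for each of 22465 genes (points), with genes past the threshold in TRβ cells in red and those past it in control cells circled. STC1 lies at 1.69 and 6.74, and 15 genes passed in both lines.

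The T3 effects of the lines overlapped in 15 genes, 11 of them higher in both (1.74 would be shared by independent lists) and 2 lower in both (0.63). SPTSSB, SPRR2G and THRSP were among the 13 that moved the same way, as were the protease gene KLK6 (1.55 in TRβ cells and 0.99 in control cells) and the glutathione transferase gene GSTA1 (1.59 and 0.78, a family of close relatives), both chosen after their values were seen. IL20 and the Wnt receptor gene FZD6, the latter also chosen so, moved in opposite directions (−0.95 and 1.21, and −0.75 and 0.37). Across genes, which are not independent replicates, the log2 changes had Pearson r = 0.08 and Spearman rho = −0.002. The number that moved the same way was 40 without control replicate 2, and 3, 1 and 0 without replicates 1, 2 and 3 of control cells with T3. It was 4, 5 and 5 without TRβ replicates 1, 2 and 3 and 8 without replicate 2 of TRβ cells with T3.

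The difference of the T3 effects tested directly whether the response differed between the lines. It passed the threshold in 2674 genes, 990 with a more positive and 1684 with a more negative change in TRβ cells. The largest differences were those of STC1 (5.05 ± 0.48, adjusted p = 1.9e-04), GPNMB (4.95 ± 0.37), OAS2 (4.74 ± 0.26), IFI6 (4.49 ± 0.84) and IFI27 (4.41 ± 0.72). On the negative side were CEACAM6 (−3.63 ± 0.44), CEACAM5 (−3.55 ± 0.43), UGT2B15 (−3.53 ± 0.26), SLC12A2 (−3.51 ± 0.24) and DKK1 (−3.40 ± 0.26). KLF9 had a difference of 0.79 ± 0.26 and ESR1 of −0.99 ± 0.34, which did not pass (adjusted p = 0.073 and 0.091). Of 36 interferon response genes 34 had a more positive change in TRβ cells (35 adjusted over the list alone), and of 29 G2 and mitosis genes 19 (25) and of 28 S phase genes 19 (23) a more negative one. The adjusted p-values of these lists were 1.4e-35, 6.0e-16 and 1.7e-12, and 0.17, 0.17 and 0.23 with an estimated correlation. HIF1A (2.59 ± 0.14), PLIN2 (1.40 ± 0.13) and SOX2 (1.28 ± 0.25) were more positive, and MYBL1 (−1.70 ± 0.16), ERBB4 (−1.92 ± 0.24) and EPCAM (−0.82 ± 0.10) more negative.

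Camera called 11 other lists for the difference, and none with an estimated correlation. Members with a more positive and a more negative difference, in that order and with the counts adjusted over the list alone in brackets, numbered 7 and 1 of 21 NF-κB targets (10 and 1), 10 and 3 of 25 hypoxia genes (12 and 3), 4 and 0 of 16 p53 targets (6 and 0) and 6 and 1 of 21 stress response genes (8 and 1). Their adjusted p-values were 8.7e-05, 0.0015, 0.0054 and 0.0063, and 0.35, 0.50, 0.35 and 0.40 with an estimated correlation. The counts were 0 and 6 of 21 luminal genes (0 and 6), 2 and 8 of 33 estrogen response genes (2 and 12), 6 and 0 of 25 thyroid hormone response genes (8 and 0) and 4 and 1 of 24 stem cell genes (4 and 1), with adjusted p-values of 0.0011, 0.0072, 0.0093 and 0.039, and 0.41, 0.61, 0.17 and 0.25 with an estimated correlation. They were 3 and 0 of 16 fatty acid genes (3 and 1), 3 and 0 of 12 fibroblast markers (5 and 0) and 1 and 0 of 13 immune cell markers (3 and 0), with adjusted p-values of 0.029, 0.011 and 0.026, and 0.50, 0.27 and 0.50 with an estimated correlation. Camera did not call the other 13 lists, of which fry called 4, the ErbB (adjusted p = 0.0015), basal (0.0019), Wnt (0.0024) and mesenchymal (0.030) lists. With all probe sets used camera called the Wnt list as lower (0.034), beside unnamed probe sets with a median difference of 0.12. The fatty acid, stem cell and stress response calls were lost without control replicate 2, at adjusted p = 0.32, 0.12 and 0.053, the estrogen call without control replicate 3 (0.057) and the immune call without control replicate 1 (0.10) or replicate 3 of TRβ cells with T3 (0.055). The fatty acid call was lost without TRβ replicate 3 (0.074), and the stem cell call without replicate 2 of control cells with T3 (0.070), TRβ replicate 2 (0.056), TRβ replicate 3 (0.054) or replicate 3 of TRβ cells with T3 (0.057).

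The difference of the T3 effects depended on scaling and on single arrays. After cyclic loess normalization 888 differences were positive and 925 negative, and centring gave 503 and 2679. The count of 2674 was 1729 without control with T3 replicate 2, 1686 without TRβ replicate 1, 1686 without TRβ replicate 2 and 4433 without control replicate 2.

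TRβ and control cells without added T3 were compared to see how the lines differed without the added ligand. STC1 was 17.6-fold lower in TRβ cells (log2 change −4.14 ± 0.34, adjusted p = 3.4e-04), at 6.91 against 11.05 ± 0.70 (SD, n = 3) in control cells. RHOB, a small GTPase gene (−2.07 ± 0.34), QSOX1, a sulfhydryl oxidase gene (−1.79 ± 0.41), and SLC7A8 (−1.78 ± 0.18) were lower. The lipid transporter gene ABCA12 (−1.60 ± 0.17), the transcription factor gene ARNT2 (−1.48 ± 0.20) and ACACB, an acetyl-CoA carboxylase gene (−1.47 ± 0.22), were also lower. CEACAM6 (3.95 ± 0.31), CEACAM5 (2.87 ± 0.30) and UGT2B15 (2.46 ± 0.19) were higher, as were the hydrolase gene ABHD2 (2.22 ± 0.19), SLC12A2 (2.07 ± 0.17) and the vesicle transport gene RAB27B (1.74 ± 0.26). In all, 549 genes were higher and 196 lower in TRβ cells. KLF9 changed by −0.25 ± 0.18, ESR1 by −0.05 ± 0.24, PGR by 0.17 ± 0.07 and DIO1 by 0.10 ± 0.07, and none of these passed.

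Of 25 hypoxia response genes 7 were lower and 3 higher in TRβ cells without T3 (14 and 4 adjusted over the list alone), with BNIP3 at −0.95 ± 0.14, HK2 at −0.86 ± 0.13 and EGLN3, an oxygen-sensing hydroxylase, at 1.31 ± 0.12. The list's adjusted p was 1.8e-04, and 0.41 with an estimated correlation. Of 16 fatty acid synthesis genes ACACB and ME1 (−1.03 ± 0.19) were lower (3 lower and 1 higher adjusted over the list alone, list adjusted p = 9.3e-04, and 0.35 with an estimated correlation). Of 33 estrogen response genes 4 were higher (7 higher and 1 lower adjusted over the list alone), including the chemokine gene CXCL12 (0.81 ± 0.09) and MYBL1 (0.65 ± 0.12). That list had an adjusted p = 0.0015, and 0.54 with an estimated correlation. The S phase list was called as higher with 0 of 28 members past the threshold (median 0.26, adjusted p = 0.0015, and 0.50 with an estimated correlation), and the ribosome biogenesis list with 2 of 20, NOP2 and NCL (2 adjusted over the list alone, adjusted p = 0.021, and 0.56 with an estimated correlation). The ribosome call was lost after cyclic loess normalization (0.31, against 8.2e-04 to 0.56 over all camera alternatives) and without control replicate 1 (0.23), control replicate 3 (0.051) or TRβ replicate 2 (0.16). The ribosome list's median of 0.15 lay within those of most random lists matched on level (−0.08 to 0.21). The estrogen call was lost without control replicate 3 (0.088), the S phase call without control replicate 1 (0.054) and the fatty acid call without control replicate 2 (0.056). Of 36 interferon response genes 1, DTX3L, was higher (0.62 ± 0.15; 0 adjusted over the list alone), and camera did not call the list (adjusted p = 0.19) or the other 21. After cyclic loess normalization, chosen after seeing the data, camera called the interferon list as lower (median −0.15, against −0.09 as deposited, adjusted p = 0.040, against 0.040 to 0.85 over all camera alternatives). The thyroid hormone response genes were called as lower without the 40% of genes with the lowest mean (0.0088). The G2 and mitosis genes were called as higher without TRβ replicate 3 (0.010), and the fibroblast markers as lower without control replicate 2 (0.011) and in 6 other alternatives (0.011 to 0.73 over all). Of these 22 lists fry called 4, the ErbB genes (adjusted p = 0.0013), thyroid hormone response genes (0.0055), Wnt targets (0.015) and fibroblast markers (0.029). Among single members of other lists, IL6 was higher by 1.17 ± 0.07, DIO2, an activating deiodinase, by 0.84 ± 0.08, AGR2 by 1.41 ± 0.13, ERBB4 by 1.65 ± 0.17 and DKK1 by 1.70 ± 0.18.

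For TRβ without T3 the count was 36 (32 higher and 4 lower) when the 6 arrays compared were fitted alone, 195 and 202 without TRβ replicates 1 and 2, and 1253 without control replicate 2. Repeated quantile normalization gave 321 higher and 298 lower genes and cyclic loess 381 and 353, against 549 and 196 as deposited.

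With T3 in both lines, the differences between TRβ and control cells were led by the interferon genes and by GPNMB and ANXA1. GPNMB was higher in TRβ cells by 4.90 ± 0.26, OAS2 by 4.52 ± 0.19, ANXA1 by 4.51 ± 0.35, SAMD9 by 3.88 ± 0.33 and PARP14 by 3.68 ± 0.24. TNFSF10, the gene of the death ligand TRAIL, was higher by 3.53 ± 0.18 (adjusted p = 1.1e-06). The largest changes on the lower side were those of IGFBP5, an insulin-like growth factor binding protein (−3.12 ± 0.37), the keratin gene KRT10 (−2.88 ± 0.31), RMND1 (−2.62 ± 0.22), HACL2 (−2.55 ± 0.42), TM4SF1 (−2.29 ± 0.12) and TNFRSF11B, the gene of osteoprotegerin (−2.28 ± 0.18). In all, 1384 genes were higher and 2208 lower. ESR1 was lower (−1.04 ± 0.24, adjusted p = 0.016), PGR changed by −0.01 ± 0.07 and KLF9 by 0.53 ± 0.18, and the last 2 did not pass.

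Of 36 interferon response genes 34 were higher (36 adjusted over the list alone), of 29 G2 and mitosis genes 25 lower (28) and of 28 S phase genes 18 lower (22). Their adjusted p-values were 2.7e-38, 1.4e-19 and 4.0e-12, and 0.17, 0.17 and 0.23 with an estimated correlation. Of 21 NF-κB targets 11 were higher (11 adjusted over the list alone), with TNFAIP3 at 1.52 ± 0.13 and IL6 at 0.76 ± 0.07 (list adjusted p = 1.5e-06, and 0.27 with an estimated correlation). Of 16 p53 targets 6 were higher (8) and of 21 stress response genes 8 higher and 1 lower (11 and 1), with PMAIP1 at 1.07 ± 0.16 and ASNS, asparagine synthetase, at 0.75 ± 0.08 (list adjusted p = 5.1e-04 and 0.0021, and 0.27 and 0.35 with an estimated correlation). Of 21 luminal genes 6 were lower (9), including KRT8 (−1.06 ± 0.10), KRT18 (−1.36 ± 0.23) and KRT19 (−1.76 ± 0.30), with list adjusted p = 0.0015, and 0.41 with an estimated correlation, and 0.080 after cyclic loess normalization (2.8e-06 to 0.41 over all camera alternatives). Of 25 thyroid hormone response genes 5 were higher and 1 lower (6 and 1), with FURIN, a protease gene, at 2.09 ± 0.39 (list adjusted p = 0.019, 0.20 with an estimated correlation and 0.076 with all probe sets used). The luminal median of −0.27 lay within those of most random lists matched on level (−0.41 to 1e-04). So did the thyroid hormone response median of 0.09 (−0.08 to 0.11). SOX2 was higher by 1.67 ± 0.18, HIF1A by 3.04 ± 0.10 and the hypoxia-inducible factor gene EPAS1 by 1.23 ± 0.12. Of 13 immune cell markers 3 were higher (3 adjusted over the list alone), including ITGAM at 0.41 ± 0.07, with list adjusted p = 0.0073, and 0.41 with an estimated correlation, and 0.13 after cyclic loess normalization (0.0040 to 0.41 over all camera alternatives). Camera did not call the other 18 lists, among them 33 estrogen response genes with 5 higher and 9 lower, 25 hypoxia genes with 7 and 8 (median −0.14, mean 0.09) and 24 stem cell genes with 5 and 0 (adjusted p = 0.12, 0.65 and 0.051). Camera called the hypoxia list as higher after cyclic loess normalization (median 0.09, adjusted p = 0.015, against 0.015 to 0.96 over all camera alternatives), and the ribosome biogenesis list as higher too (median 0.20, 7.7e-04, against 7.7e-04 to 0.85). The estrogen list was called as lower with all probe sets used (0.0039), in the groups compared only (0.040) and without control replicate 2 (0.040), against 0.0039 to 0.78 over all camera alternatives. Alternatives also called the stem cell list as higher (4 alternatives, 0.036 to 0.27 over all), the oxidative phosphorylation list as lower with all probe sets used (0.0099) and without replicate 2 of TRβ cells with T3 (0.044), and the fibroblast markers as higher without that array (0.045). The unnamed probe sets, which enter when all probe sets are used, had a median change of 0.09. Of these 18 lists fry called 6, the stem cell (adjusted p = 5.0e-04), basal (0.0013), mesenchymal (0.0030), Wnt (0.0066), fibroblast (0.0089) and hypoxia (0.030) lists.

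The count of 3592 genes for TRβ with T3 was 2301 and 2155 without replicates 1 and 2 of control cells with T3, and centring gave 749 higher and 3546 lower. After cyclic loess normalization 1292 genes were higher and 1523 lower, 2284 of them among the 3592.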

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

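The tests of RNA from other cell types, of a batch, of T3 acting through the transduced receptor, of mislabelled arrays, of the TRβ arrays shared by comparisons, of left-out control arrays and of the labels of the control line were chosen only after the results were seen, as was cyclic loess normalization, and the tests of other cell types, of a mislabelled treated array and of shared TRβ arrays were revised after their first results were seen. The difference of the T3 effects between the lines, tested as an interaction, passed the threshold in 2674 genes. The 5 largest differences in each direction were STC1 (5.05), GPNMB (4.95), OAS2 (4.74), IFI6 (4.49) and IFI27 (4.41), and CEACAM6 (−3.63), CEACAM5 (−3.55), UGT2B15 (−3.53), SLC12A2 (−3.51) and DKK1 (−3.40).

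The same interaction was called by camera for 14 lists, with these median differences on the log2 scale. The positive ones were 2.17 for interferon response genes, 0.33 for NF-κB targets, 0.33 for hypoxia response genes, 0.32 for p53 targets, 0.22 for stress response genes, 0.19 for thyroid hormone response genes, 0.19 for stem cell and pluripotency genes, 0.19 for immune cell markers, 0.15 for fibroblast markers and 0.15 for fatty acid synthesis genes. The negative ones were −1.12 for G2 and mitosis genes, −0.72 for S phase genes, −0.48 for luminal genes and −0.28 for estrogen response genes. After cyclic loess normalization the positive medians were, in the same order, 2.36, 0.31, 0.56, 0.63, 0.49, 0.14, 0.07, 0.05, 0.04 and 0.39. The negative ones were then −0.76, −0.53, −0.17 and −0.11. Without control replicate 2 the fatty acid, stem cell and stress response medians were 0.065, 0.15 and 0.14. None of the 14 calls held with an estimated correlation. As deposited, 3 of these medians lay within those of most random lists matched on level. They were those of the luminal genes (−0.54 to −0.03), fibroblast markers (−0.035 to 0.22) and immune cell markers (−0.02 to 0.24). After cyclic loess normalization the estrogen, luminal, stem cell, fibroblast and immune lists were no longer called, at adjusted p = 0.080, 0.13, 0.14, 0.27 and 0.48, and the MAPK response, oxidative phosphorylation and ribosome biogenesis lists were newly called as higher, at 0.026, 0.030 and 0.041. Over all camera alternatives the adjusted p of these 8 lists ran up to 0.61, 0.41, 0.25, 0.61, 0.73, 0.74, 0.99 and 0.92, from 6.1e-05, 4.8e-06, 0.023, 0.0048, 0.014, 0.026, 0.030 and 0.041. Among the 42204 probe sets with no gene named here, which the comparisons did not use, 1775 were higher and 1086 lower with T3 in TRβ cells, against 2 and 1 with T3 in control cells.

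The rise of the interferon response genes in TRβ cells with T3 was weighed first. A level-dependent shift of those arrays as the whole cause is argued against by the median of the list after cyclic loess normalization, 2.06, with 34 of 36 members past the threshold. RNA from fibroblasts, immune or endothelial cells is argued against by the median change of their 35 markers, 0.0595 after that normalization (SD 0.16 across markers). Of these, 7 that are abundant in those cell types lay between −0.07 and 0.18, and the highest, CD68, at 0.61. The fibroblast, immune and endothelial lists had median levels of 4.26, 4.01 and 4.21, below the array medians of 4.38 to 4.58. Little such RNA was likely from the start in an established line, so this test adds little. T3 acting through the transduced receptor is a hypothesis that these values leave open, since 34 of 36 members passed in the difference of the T3 effects. The labels give a batch for these arrays in 0 lines, so none was tested.

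Control replicate 2 stood apart from the other control arrays, with a mean of the 2 median absolute differences of 0.21, against 0.13 between the other controls. A level-dependent shift as the whole cause is argued against by the same distance after cyclic loess normalization, 0.198, against 0.118 between the other controls. A mislabelled TRβ array is argued against by its THRB value of 5.12, against 5.98 to 6.26 in the TRβ line, and a mislabelled T3-treated control array as the whole cause by its highest correlation with a treated control array, 0.977 across probe sets, against 0.989 to 0.992 between those arrays, although it correlated less with the untreated controls (0.965 with each), so a wrong label beside another fault stays open. Its STC1 value of 11.79 lay between the other untreated controls (10.40 to 10.95) and the treated ones (12.40 to 13.28), and its KLF9 value of 4.42 among the other untreated controls (4.30 to 4.61). No biological explanation was tested, and other differences in handling or culture stay open.

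Of 480 genes past the threshold in TRβ cells without T3 and with T3 in TRβ cells, 442 moved in opposite directions, STC1, CEACAM6 and SLC12A2 among them, 374 higher and then lower (69.1 expected of independent lists) and 68 lower and then higher (16.2 expected), and both comparisons hold the same 3 TRβ arrays. The covariance of the log2 changes was −0.038 (r = −0.33), against a median of −0.0065 and a range of −0.041 to 0.023 in 100 simulations of unchanged groups (median r = −0.35), so part or all of the excess may come from the shared arrays, which 3 arrays are too few to split. Each simulated array was a random mix of the 3 deviations of its own group, so its genes moved together and single simulations swung widely. In these simulations up to 1819 genes passed in both comparisons and moved in opposite directions, more than the 442 observed. That maximum reflects the setting as well as the shared arrays, so no conclusion is drawn from it. Control replicate 2 as the cause is argued against by 710 such genes without it. A reversal that T3 brings in control cells too stays open, although 36.2% of the 442 genes moved there as they did with T3 in TRβ cells, against 49.1% of all genes called with T3 in TRβ cells and below the bound planned to exclude it, because the same control arrays served to choose the genes. With genes chosen without control replicate 1, 2 or 3 and the T3 effect in control cells measured against that array, the shares were 43.4%, 61.7% and 53.4%, above, above and below those of all genes called with T3 in TRβ cells (34.4%, 56.6% and 56.2%), with median changes of −0.06, 0.12 and 0.03 against 0.72, 0.62 and 0.66 in TRβ cells.

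For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split was the 1 of 10 with as many genes for each, with 4687, 26, 745 and 3592 genes for T3 in TRβ cells, T3 in control cells, TRβ without T3 and TRβ with T3, and the highest other split gave 0 for each. For the difference of the T3 effects, 3 of 100 drawn splits of treatment within each line gave as many as the real 2674 genes, the real one included, and the highest other gave 3094. All 9 drawn splits that kept the true split of the TRβ line gave 1583 to 3094 genes and the other 91 gave 0, so the share of 3 in 100, which the planned rule would take to exclude chance, follows the TRβ line and does not exclude it for the difference. With that line's true split, 6 of all 20 assignments of treatment in the control line gave at least 2674 genes, the real one included, and the highest gave 3284.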

How the results depend on the processing

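Cyclic loess normalization was chosen after seeing the data and the other alternatives before. The numbers of genes past the threshold moved by over 1.5 times as follows. A minimum change of 1.5-fold gave 2104, 322 and 1697 genes for T3 in TRβ cells, TRβ without T3 and TRβ with T3. The 0.01 threshold gave 2317, 0, 1029, 187 and 1656 for T3 in TRβ cells, T3 in control cells, the difference, TRβ without T3 and TRβ with T3. Adjusting over all probe sets, which adds tests, gave 3 for T3 in control cells, 1677 for the difference and 338 for TRβ without T3. Fitting only the groups compared, with fewer arrays behind the spread, gave 0 for T3 in control cells and 36 for TRβ without T3. Both hold the untreated control group. The counts without that group rose, by less than 1.5 times, to 5645 for T3 in TRβ cells and 4544 for TRβ with T3. The untreated control group had the largest median SD of a gene (0.160, against 0.093 to 0.104 in the others). The pooled spread may therefore be too small for comparisons that hold it. The trended and robust prior gave 14 for T3 in control cells and array weights 5687 for TRβ with T3, and the cause was not tested. The 13 genes that moved the same way with T3 in both lines became 2 (all probe sets), 22 (quantile), 6 (prior), 21 (weights), 0 (groups compared only), 0 (0.01 threshold) and 20 (loess). The replicate numbers shared by the groups did not pair the arrays over all groups together, since the 18 same-number pairs correlated at −0.29 to 0.44 in their deviations, 7 of them over 0.1, and arrays correlated best with their own number in 14 of 36 cases. Between TRβ cells without and with T3 the same-number pairs correlated at 0.15, 0.09 and 0.15. The other pairs of these groups correlated at −0.10 to −0.02, so a pairing within the TRβ line stays open. The replicate block gave 6 genes for T3 in control cells and an overlap of 4, and moved no other count by over 1.5 times. Leaving out an array gave 2934 to 6300 genes for T3 in TRβ cells, 0 to 72 for T3 in control cells, 1686 to 4433 for the difference, 195 to 1253 for TRβ without T3, 2155 to 5087 for TRβ with T3, 0 to 40 for the overlap and 42 to 50 called lists. Camera called 47 of 135 list tests, and 0 with an estimated correlation. Fry called 58, which left out 9 of the 47 and added 20. With all probe sets used camera lost 7 of the 47 calls and gained 7. Without the 40% of genes with the lowest mean it lost 8 and gained 1. After repeated quantile normalization it lost 10 and gained 6. Except for those named above, the medians of called lists lay outside those of most random lists matched on level. Directions turned under cyclic loess for the oxidative phosphorylation list (0.24 for T3 in TRβ cells and 0.27 for the difference), the ribosome biogenesis list (0.15 for the difference) and NPM1 (0.0275 and 0.0342), and without control replicate 2 for the estrogen list with T3 in control cells (−0.15 to 0.04 over the left-out arrays). The cause was not tested. Of 14927 values of named genes under the alternatives, 13730 kept their direction and side of the threshold, 1019 fell short of it, 176 passed newly and 2 turned, and of 3240 list values 3047, 131, 58 and 4 did. Values past the threshold in neither setting counted as kept whatever their sign. No background level is given for the arrays, so how far dim genes can show a change is unknown.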

Other observations

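The interferon genes themselves were looked at after the rise of their response genes was seen. IFNL1, a type III interferon, averaged 6.54 in control cells, 5.85 with T3, 5.19 in TRβ cells and 8.75 in TRβ cells with T3. With T3 in TRβ cells IFNL2 rose by 2.57 ± 0.24 (adjusted p = 4.7e-05 by limma with Benjamini-Hochberg adjustment), IFNL3 by 2.12 ± 0.19 and IFNB1, a type I interferon, by 1.86 ± 0.20, and the chemokine gene CCL5 rose by 1.18 ± 0.23. IFNL2 and IFNL3 are near-identical copies, so their signals cannot be assigned to either. IFNA1 (0.33 ± 0.20) and IFNG (0.16 ± 0.10) did not pass the threshold.

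Small nucleolar RNA genes, which guide the modification of ribosomal RNA, were measured for 227 genes. Their median log2 change with T3 in TRβ cells was 0.25, against −0.003 for the 16837 protein-coding genes, 0.11 for microRNA, 0.09 for long noncoding RNA and 0.20 for 78 pseudogenes. Other genes of the same signal level had a median of 0.04 (0.01 to 0.07 in 95% of 1000 draws), and after cyclic loess normalization the median of the small nucleolar RNA genes was 0.17, both compared after the result was seen. The rise was not particular to them. After that normalization pseudogenes had a median of 0.17 and 22 small nuclear RNA genes 0.16 (0.01 as deposited). Pseudogenes also lay above genes of their level (0.20 against 0.02, −0.04 to 0.07). The median deviation of the small nucleolar RNA genes was 0.15 on each of the 3 arrays of TRβ cells with T3 and between −0.09 and 0.01 on the other 9. In control replicate 2 they lay 0.12 above the mean of the other controls in the median, while microRNA genes lay at −0.13. KCNQ1OT1, a nuclear RNA of the list that was not tested, fell by 0.64 ± 0.11 with T3 in TRβ cells, and MALAT1 changed by 0.22 ± 0.21.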
